A study of Mus musculus with 10 samples.

How the data were processed

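The deposited table gives 1 intensity per probe set and array, on a linear scale, for 10 arrays of RNA from whole brain at postnatal day 0. The authors' steps before deposit, such as the algorithm that summarised the probes, are not given in the sources used here. In the deposited intensity values the mean of every array, after trimming 2% at each end, lies at 500.3, so the arrays had been scaled to each other before deposit, and no value is at or under 0. The values were used without further normalization. No detection calls, scanner files or scan dates were used here, so batches of hybridisation could not be examined.

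Arrays were grouped by the genotype and cross in their labels into XmO (replicates 1, 2 and 7), XX_Paf (1, 2 and 3), XpO (15 and 18) and XX_InX (1 and 19). The labels do not say that each array is a separate animal, or whether RNA was pooled; if samples share animals or litters, the p-values then measure only the spread between these samples. The number of arrays limits the precision of every value. If the crosses are written mother x father, which the labels do not state, they are reciprocal, so XmO against XpO and XX_Paf against XX_InX also differ in the parental origin of the autosomes.

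Of 12488 probe sets, 66 were controls and were left out. The probe table gave 1 gene symbol for 10833 of the rest, several for 396 and none for 1193; probe sets with several symbols name no gene here. Chromosomes came from a reference gene table of assembly GRCm38.p6, by gene identifier, for 10817 of the 10833, with 353 probe sets on the X and 11 on the Y. Intensities under the 10th percentile of all values (15) were raised to it, values were taken to log2, and the 8695 probe sets whose mean log2 value reached the 30th percentile were tested.

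A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 6 residual degrees of freedom), and 6 contrasts were tested: XO against XX with equal weight for each cross, XmO against XX_Paf, XpO against XX_InX, XmO against XpO, the difference of the monosomy effects between crosses, and XX_Paf against XX_InX. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05. Gene lists (31 fixed, of which 25 had at least 3 tested genes) were tested with camera, with a preset correlation of 0.01 and again with an estimated one, and with fry, each gene by its probe set of highest mean; fry's call was the same as that of camera with an estimated correlation in every contrast. Of the calls made with the preset correlation, the escape list held with an estimated correlation in XO against XX and in XmO against XX_Paf (in neither without Utp14a), and the cell cycle list did not in XmO against XpO. The X-linked probe sets were compared with the autosomal ones with camera, adjusted over the 6 contrasts. The lower bound for Xist took, on each XO array, the higher of Xist itself and the brightest of the 11 Y-linked probe sets as background. For other named probe sets with a group at or below that background on every array, that group was set to it, array by array, and the others kept their values. Such a bound allows for the background but not for the spread between arrays. These bounds were added after the results were seen.

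Genes were named by a rule. In each contrast it takes up to 10 called probe sets in each direction with the largest fold changes. A direction with fewer than 10 called is filled to 5 with the probe sets of smallest p whose groups do not overlap (for the difference between crosses, whose effects have opposite signs). It adds all measured members of the lists of X inactivation RNA, escape, pseudoautosomal, Xlr and Y-linked genes, and up to 4 members of any other list that passed. Where a named probe set is not the gene's brightest, both values are given. Genes outside the rule (Prl in XmO against XX_Paf, others past the threshold over a list alone, Meg3 and neighbours of Hccs) were chosen after their values were seen. Contrasts, lists and the main alternatives were fixed before the data were examined. The naming rule was fixed then too, except in its choice among several probe sets of a gene. Such a gene was to be named by its brightest probe set, but the rule as applied took whichever probe set ranked first.

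The steps from the model fit onward were tested on simulated data with the real probe sets' means and the spreads that limma estimated. Noise was drawn independently for each probe set and array, so correlation between probe sets was not simulated. Normalization, floor and filter were not simulated either, and the shares below hold for such data only. Of probe sets changed by a log2 value of 1, the share recovered was 85.1% for XO against XX, 68.7% for XmO against XX_Paf, 58.2% for XpO against XX_InX, 58.2% for XmO against XpO, 28.4% for the difference between crosses and 64.2% for XX_Paf against XX_InX, each of 8695 probe sets; with no change simulated, 0 were called by limma, and 4.40% to 5.19% had an unadjusted p under 0.05. Alternatives were quantile normalization and median scaling, no floor or the 25th percentile, no filter or the 50th percentile, eBayes without trend, array weights, only the groups of a comparison, the cross ignored, blocks by replicate number (statmod 1.5.0), other ways to treat several probe sets of a gene, and leaving out each array. The first principal component as a covariate, leaving out XpO 18 and XX_InX 1 together, and the escape list without Utp14a, were chosen after seeing the data. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.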

Results

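RNA of the whole brain of newborn mice (postnatal day 0) was hybridised to 10 Affymetrix MG-U74Av2 arrays, each reporting 12488 probe sets. Animals with a single X chromosome (39 chromosomes, XO) were compared with XX females (40 chromosomes). XmO animals, whose X is maternal by their name in the labels, and XX_Paf females came from the cross written as C57BL/6J x C3H/Paf, with 3 arrays each. XpO animals, with a paternal X, and XX_InX females came from the cross written as In(X)/C3H x C57BL/6J, with 2 arrays each. The labels do not say whether each array holds 1 animal or a pool. Every array had a trimmed mean intensity of 500.3, and the arrays correlated with each other at 0.927 to 0.969 (Pearson's r of log2 intensities across probe sets, which are not independent replicates). The first principal component took 25.6% of the variance and separated XX_Paf (9.77 to 23.6) from XX_InX (-22.4 to -9.54) and XmO (-8.01 to 8.73), while XpO 18 lay at -27.4 and XpO 15 among XX_Paf. Where every array of a group was at or below the brightest Y-linked probe set of that array, a value against that group is given as a bound (at least). Values are mean intensity ± SD over the arrays of a group, and adjusted p-values are those of limma.

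The first comparison asked what loss of 1 X chromosome changes in the newborn brain, over both crosses. Xist, the noncoding RNA that coats the inactive X, checks the labels: its intensity was 3708 ± 392 in XX_Paf (n = 3) and 2172 ± 705 in XX_InX (n = 2), but 25.2 ± 4.90 in XmO (n = 3) and 45.3 ± 6.58 in XpO (n = 2). On 4 of the 5 XO arrays Xist was below the brightest of the 11 Y-linked probe sets, which have no template in these animals, and on XpO 15 it was above it (40.6 against 33.6). The fall is therefore given as a bound, against the higher of the values on each XO array: Xist was at least 42.1-fold lower in XmO than in XX_Paf and at least 36.3-fold lower in XpO than in XX_InX (adjusted p = 2.28e-10 over both crosses, lower in 5 of 5 XO arrays than in every XX array). Genes known to escape X inactivation fell as a group. All 6 measured members of that list had lower estimates in XO, with a mean log2 fold change of -0.34 (camera, adjusted p = 4.24e-07, and adjusted p = 0.0291 with an estimated correlation). Without Utp14a, which was below the brightest Y-linked probe set on 2 of 3 XmO, 1 of 2 XpO and 1 of 2 XX_InX arrays, the mean was -0.23 (camera, adjusted p = 1.27e-05), and the list did not pass with an estimated correlation (adjusted p = 0.0540). 1 of the 6 members passed when adjusted over the list alone and 0 did so by limma over all probe sets. That 1 gene was Eif2s3x, the X-linked gamma subunit of translation initiation factor eIF2. It was at 4564 ± 206 in XmO and 5769.6 ± 261 in XX_Paf, and at 3843 ± 125 in XpO and 5782 ± 451 in XX_InX (log2 fold change -0.46, SE 0.07; adjusted p = 0.104 over all probe sets and 1.44e-04 over the list alone). The other 5 members did not pass either adjustment. The ribosome assembly gene Utp14a had a log2 fold change of -0.90 (SE 0.33; -0.50 without XpO 18 and -1.31 without XpO 15) and the histone demethylase gene Kdm6a -0.27 (SE 0.12). The RNA helicase gene Ddx3x had -0.21 (SE 0.11), biglycan (Bgn) -0.18 (SE 0.11) and the deubiquitinase gene Usp9x -0.04 (SE 0.08). The second Ddx3x probe set had the opposite sign, 0.43.

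**Figure D1:**
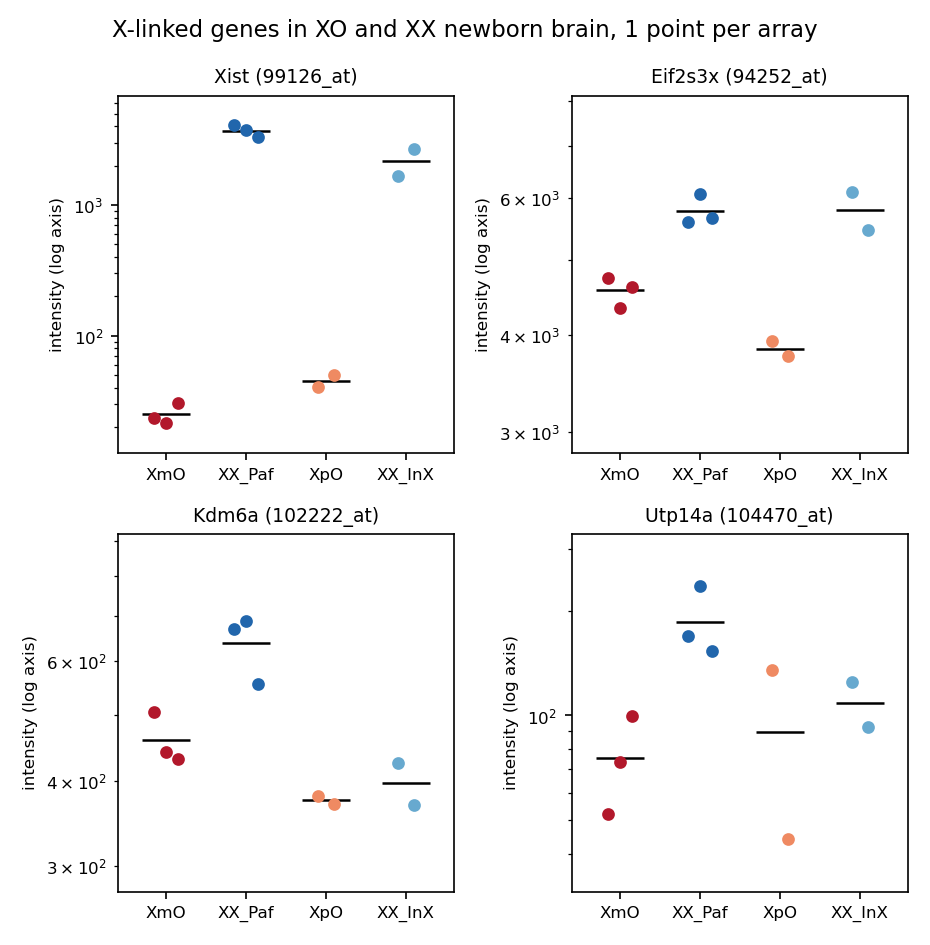
Intensity on a log axis of the probe sets of Xist, Eif2s3x, Kdm6a and Utp14a; each point is 1 array of the group on the x axis and each line is the group's mean. The 5 XO arrays have Xist between 21.3 and 49.9 and the 5 XX arrays between 1673 and 4082, and Eif2s3x lies lower in each XO array than in every XX array, while the XpO and XX_InX arrays overlap for Kdm6a and Utp14a.

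Outside Xist, no probe set passed over all 8695 tested: 1 was called, and 226 had an unadjusted p under 0.05 where 435 are expected by chance. By the rule for naming genes, the probe sets of smallest p whose groups did not overlap within either cross are given as values that did not pass. Higher estimates in XO were those of the vesicle coat gene Sec23b (1 probe set, at least 2.19-fold, 1.83 without XX_Paf 2), the RNA-binding gene Rbm6 (0.84), the cadherin Celsr2 (0.96), the axonal kinesin Kif1a (0.49) and Rasal3 (at least 1.36-fold, 1.29 without XpO 18). Lower estimates besides Eif2s3x were those of prolactin (Prl, -1.34, SE 0.30, with 2 of 3 XmO and 1 of 2 XpO arrays below their brightest Y-linked probe set), the neuronal transcription factor Sox11 (-0.60) and Tbrg4 (-0.56). Sec23b's brighter probe set gave -0.04, and the brighter probe sets of Celsr2, Sox11 and Tbrg4 gave 0.09, -0.19 and -0.03. Prl was the 1 member of the pituitary list that passed when adjusted over the list alone (adjusted p = 0.00460), and the cortical transcription factor Neurod6 was the 1 member of the forebrain list (0.42, adjusted p = 0.0397 over the list alone). The count of probe sets rose to 3 without XpO 15 or XX_InX 19 and to 2 without XX_InX 1, with Xist called each time.

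The X-linked probe sets as a whole did not pass against the autosomal ones in any of the 6 contrasts. In XO against XX, over 241 X-linked probe sets the median log2 fold change was -0.01, which lay -0.00859 from the median of 7692 autosomal probe sets (camera, adjusted p = 0.770 over the 6 contrasts for the X-linked set), and 127 of the 241 had a lower estimate in XO. Within the crosses the difference between the X-linked and autosomal medians was -0.0250 for XmO against XX_Paf (camera, adjusted p = 0.319) and 0.0217 for XpO against XX_InX (camera, adjusted p = 0.538). It was -0.000322 for XmO against XpO (camera, adjusted p = 0.655) and -0.0505 for the difference between crosses, where the X median (-0.04) ranked 2nd lowest of 20 chromosomes. For XX_Paf against XX_InX it was 0.0749, with the X median (0.06) over that of every autosome (highest 0.05, chromosome 13; camera, adjusted p = 0.319 here and in the difference between crosses). In XO against XX, X-linked genes with neural functions went both ways, 10 up and 10 down in estimate (camera, adjusted p = 0.762).

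**Figure D2:**
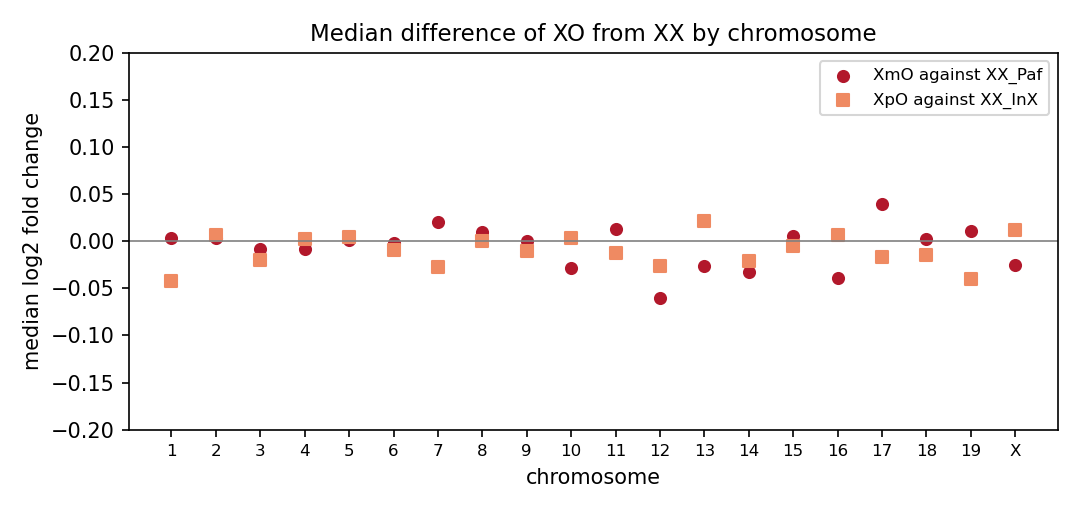
Median log2 fold change of the tested probe sets on each chromosome (x axis), for XmO against XX_Paf (circles) and XpO against XX_InX (squares). The X lies at -0.03 and 0.01, inside the range of the autosomes, which run from -0.06 (chromosome 12) to 0.04 (chromosome 17) and from -0.04 (chromosome 1) to 0.02 (chromosome 13).

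Within the Paf cross, XmO animals lacking the paternal X were set against XX_Paf females. Besides Xist, Hccs fell: this X-linked gene, which encodes the enzyme that attaches heme to cytochrome c, had an intensity of 374 ± 20.5 in XmO and 1200.2 ± 184 in XX_Paf (n = 3 each; log2 fold change -1.67, SE 0.15, adjusted p = 3.87e-04), against 428 ± 18.6 in XpO and 353 ± 53.5 in XX_InX (n = 2 each). Its second probe set had an estimate of -1.36 (SE 0.37, adjusted p = 0.808), with 2 of the 3 XmO arrays below their brightest Y-linked probe set, and was at 67.8 ± 31.8 in XmO, 162 ± 6.10 in XX_Paf, 113 ± 52.6 in XpO and 122 ± 0.212 in XX_InX. The escape list fell with all 6 estimates lower in XmO, mean -0.47 (camera, adjusted p = 8.44e-06, and adjusted p = 0.0488 with an estimated correlation). Without Utp14a the mean was -0.30 (camera, adjusted p = 1.87e-04), and the list did not pass with an estimated correlation (adjusted p = 0.0951). Over the list alone 4 members passed: Utp14a (-1.33, SE 0.42), Kdm6a (-0.47, SE 0.15), Ddx3x (-0.38, SE 0.14; other probe set 0.42) and Eif2s3x (-0.34, SE 0.09). None of these passed over all probe sets, and Utp14a was below its array's brightest Y-linked probe set on 2 of the 3 XmO arrays. In all, 2 probe sets were called and 481 had an unadjusted p under 0.05. Among those that did not pass, higher estimates in XmO were found for the transcription factor Tef (1.35), Spag7 (0.90) and trefoil factor Tff1 (1.09). The phosphatase gene Ptprv (at least 1.95-fold, 1.68 without XmO 7) and 1 probe set of the ribosomal protein gene Rps4x (1.68, brighter probe set -0.01) were also higher. Lower estimates were found for Aebp1 (at least 1.63-fold, 1.43 without XmO 1), the DNA polymerase delta subunit gene Pold2 (-1.34) and 4931406C07Rik (-2.03, brighter probe set -0.13). Prl passed when adjusted over the pituitary list alone (-1.54, adjusted p = 0.00983), with 2 of 3 XmO arrays below their brightest Y-linked probe set, as for 4931406C07Rik. Maoa, the monoamine oxidase A gene, was the 1 X-linked neural gene past the threshold over its list alone (0.44, adjusted p = 0.0438 over the list alone). The count was 4 without XmO 2 and 3 without XX_Paf 3, with Xist and Hccs called in every leave-out.

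Within the In(X) cross, XpO animals lacking the maternal X were set against XX_InX. Xist fell (at least 36.3-fold, adjusted p = 2.85e-07) and was the 1 probe set called; 294 had an unadjusted p under 0.05. Of the escape genes, 5 of 6 had lower estimates, with a mean of -0.21, and the list did not pass (camera, adjusted p = 0.104, and adjusted p = 0.430 with an estimated correlation). Eif2s3x passed when adjusted over the list alone (-0.59, SE 0.11, adjusted p = 9.43e-04), while Kdm6a (-0.08, SE 0.18), Ddx3x (-0.04, SE 0.17) and Utp14a (-0.48, SE 0.51) did not. These signs rested on single arrays: Utp14a was 0.33 without XpO 18 and -1.28 without XpO 15, Ddx3x 0.07 without XpO 18 and Kdm6a 0.03 without XX_InX 1. Neurod6 passed when adjusted over the forebrain list alone (0.70, adjusted p = 0.0255). Among the values that did not pass over all probe sets, Ptprv was at 24.1 ± 8.77 in XpO and 226 ± 25.8 in XX_InX (at least 4.25-fold lower; 2.70 without XpO 15). The retinol-metabolising Adh7 was at 133 ± 37.7 and 428 ± 3.75, and 1 probe set of the ubiquitin ligase gene Nedd4 at 24.3 ± 5.30 and 179 ± 96.7 (at least 3.11-fold lower, 1.98 without XpO 15; brighter probe set 0.17). Higher estimates in XpO were those of the ABC-family gene Abcf2 (at least 2.39-fold, 1.44 without XpO 15) and Sec23b (at least 1.80-fold, 1.39 without XpO 18, brighter probe set -0.14). The liprin Ppfia4 (1.32), the chromatin-binding gene Rcc2 (1.33, brighter probe set 0.18) and the CCA-adding tRNA nucleotidyltransferase gene Trnt1 (0.86) were also higher. Leaving out 1 array raised the count to 4 (XX_InX 19), 3 (XpO 15, XX_InX 1) or 2 (XpO 18), with Xist called each time. Across probe sets, which are not independent replicates, the fold changes of this comparison and of XmO against XX_Paf, which share no array, correlated at -0.0946, and 43 of the 60 splits of the arrays within crosses gave a correlation at least as high.

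XmO against XpO addresses the parental origin of the single X; the direction of the cross differs with it. Cmip, which encodes a c-Maf-inducing adaptor protein, fell on 1 of its probe sets, which was at 787 ± 95.3 in XmO (n = 3) and 2314 ± 299 in XpO (n = 2; log2 fold change -1.56, SE 0.14, adjusted p = 7.65e-04), and at 714 ± 52.5 and 2309 ± 26.7 in the XX females of the same crosses. Its brighter probe set was at 7144 ± 264 and 7628 ± 159 (-0.09, SE 0.09). Cell cycle genes passed as a list: 19 of 22 had lower estimates in XmO (camera, mean -0.23, adjusted p = 0.00212), which was lost at adjusted p = 0.225 with an estimated correlation, and none passed when adjusted over the list alone. The members of smallest p were cyclin A2 (Ccna2, -0.49), Cdk1 (-0.44), the replication helicase subunit gene Mcm4 (-0.55) and Cdc20 (-0.26). Without XpO 18 the list had adjusted p = 0.0948, and 0.110 without XpO 18 and XX_InX 1 together. The blood markers Hbb-b2 and Hba-a1, the adult beta and alpha globin genes, passed when adjusted over the erythroid list alone (adjusted p = 0.00133 and 0.00478). Hbb-b2 was at 2779 ± 843 in XmO and 1084 ± 36.1 in XpO, and Hba-a1 at 10396 ± 2419.9 and 5327 ± 1112. A tested probe set shared by Hba-a1 and Hba-a2 had a log2 fold change of 0.29, and 1 shared by the beta globin genes had 0.67. Neither Hbb-b2 nor Hba-a1 passed over all probe sets, nor did the cell cycle inhibitor gene Cdkn1a (-1.24, adjusted p = 0.111), interferon-induced Ifitm3 (-0.99) or the tubulin gene Tubb4a (-0.56). Nor did Actb (-0.85; brighter probe set -0.56), the splicing factor gene Rbm39 (1.22; brighter probe set 0.28), Nedd4 (at least 2.65-fold higher in XmO, 1.68 without XpO 15; brighter probe set -0.22), Adh7 (1.32) or Ptprv (at least 2.75-fold higher in XmO, 1.75 without XpO 15). Of the imprinted genes expressed from the maternal allele, the noncoding RNA Meg3 had the smallest p (0.74, SE 0.23, adjusted p = 0.101 over the list alone). In all 1 probe set was called and 420 had an unadjusted p under 0.05. The count was 7 without XpO 15, 4 without XmO 1 and 2 without XpO 18, with Cmip called each time. It was 0 by limma without XpO 18 and XX_InX 1 together, where Cmip had adjusted p = 0.0524.

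**Figure D3:**
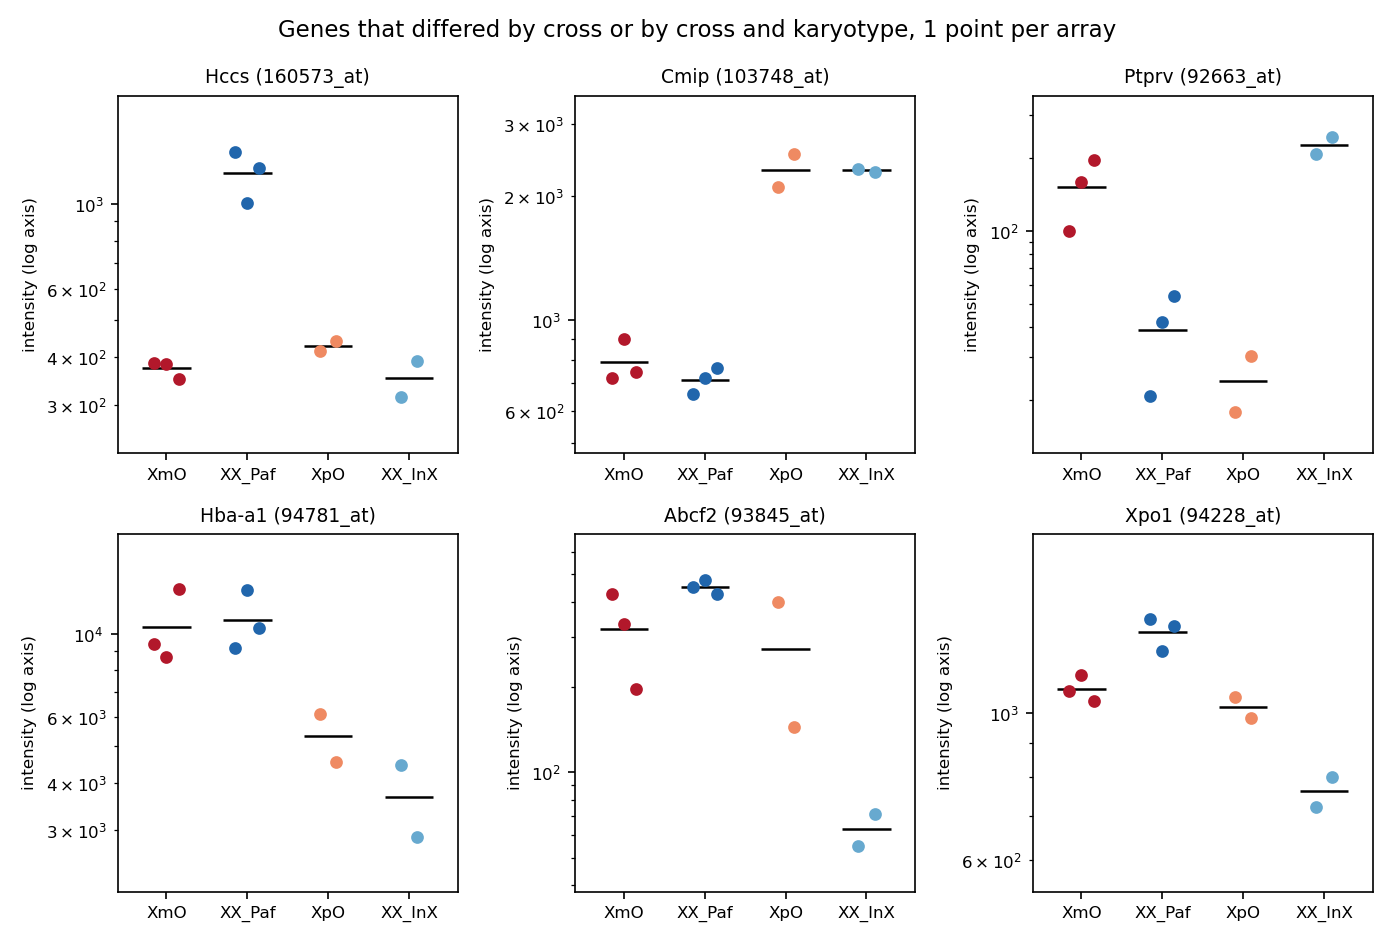
Intensity on a log axis of 6 probe sets named in the comparisons of crosses; each point is 1 array of the group on the x axis and each line is the group's mean. Hccs (the brighter probe set) is high in XX_Paf alone, Cmip (the probe set that fell) is at most 896 in the 6 arrays of the Paf cross and at least 2103 in the 4 of the In(X) cross, Ptprv is low in XX_Paf and XpO, and Hba-a1 is higher in the arrays of the Paf cross.

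The difference between the monosomy effects of the 2 crosses was tested next. It removes what the XO and XX animals of a cross share, but not a trait of the X that is lost, which differs between the crosses. This difference passed for Hccs and Ptprv. The Hccs effect was -1.67 in the Paf cross and 0.28 in the In(X) cross (difference -1.95, SE 0.24, adjusted p = 0.0219). Ptprv, a receptor-type tyrosine phosphatase gene, was at 151 ± 48.5 in XmO and 38.9 ± 16.6 in XX_Paf (n = 3 each), and at 24.1 ± 8.77 in XpO and 226 ± 25.8 in XX_InX (n = 2 each; adjusted p = 0.0313). All XX_Paf and XpO arrays were below their brightest Y-linked probe set, so the difference is at least 3.05 in log2 (2.39 without XpO 15). 2 probe sets were called and 514 had an unadjusted p under 0.05. Both calls ended without XmO 2, XmO 7 or XX_InX 1 (highest adjusted p 0.140 for Hccs, without XX_InX 1, and 0.209 for Ptprv, without XmO 7). Ptprv's also ended without XpO 15, XX_InX 19 or XX_Paf 2, with adjusted p of 0.0842, 0.121 and 0.0727, and 4 probe sets were called without XpO 18. With a higher estimate in the Paf cross but no call came Nedd4 (at least 2.20, 1.55 without XpO 15; brighter probe set -0.39), Adh7 (2.18), the copper transporter gene Atp7b (2.37, with 2 of 3 XX_Paf and 1 each of the XmO and XpO arrays below their brightest Y-linked probe set) and Rgs3 (0.68). With a lower one came Abcf2 (at most -1.83, -1.10 without XpO 15), 4931406C07Rik (-2.91; brighter probe set -0.23), perlecan (Hspg2, -2.15) and gasdermin E (Gsdme, -1.20). For 4931406C07Rik, 2 of 3 XmO and 1 of 2 XX_InX arrays were below their brightest Y-linked probe set. Its difference was -2.27 without XX_InX 1 and -3.56 without XX_InX 19. The escape list did not differ between the crosses by its test (mean -0.26, camera, adjusted p = 0.428, and 0.878 with an estimated correlation), nor did Eif2s3x (0.25, adjusted p = 0.860).

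XX_Paf against XX_InX gives the difference between the crosses in XX females, the background for XmO against XpO. 6 probe sets rose in XX_Paf and 1 fell. The adult alpha globin gene Hba-a1 was at 10866 ± 2001 in XX_Paf (n = 3) and 3674 ± 1133 in XX_InX (n = 2; log2 fold change 1.58, SE 0.22, adjusted p = 0.0211), and Hbb-b2 was at 2973 ± 679 and 1162 ± 327 (adjusted p = 0.0798, and 5.05e-04 over the erythroid list alone). A tested probe set shared by Hba-a1 and Hba-a2 was at 1954 ± 487 and 1662 ± 194 (log2 fold change 0.21, limma adjusted p = 0.658). A tested probe set shared by the beta globin genes had 1.08 (limma adjusted p = 0.0948). The erythroid list did not pass (camera, adjusted p = 0.824, and adjusted p = 0.954 with an estimated correlation). Hccs rose by 1.76 (SE 0.17, adjusted p = 7.62e-04; other probe set 0.41, SE 0.41). Abcf2 rose at least 4.50-fold (4.37 without XX_Paf 2), with both XX_InX arrays below their brightest Y-linked probe set, and the heterochromatin protein 1 beta gene Cbx1 by 1.73 (SE 0.28). Gsdme rose by 1.16 (SE 0.17; its other probe set 0.05) and the nuclear export receptor gene Xpo1 by 0.80 (SE 0.13), with adjusted p from 0.0211 to 0.0475. Cmip fell on the same probe set (-1.70, SE 0.14, adjusted p = 2.83e-04), and the brighter one had -0.23 (SE 0.09). Values that did not pass were lower in XX_Paf for Actb (-0.97, brighter probe set -0.46), Ptprv (at least 3.01-fold, 2.71 without XX_Paf 1), the phospholipid transfer protein gene Pltp (-0.67) and the semaphorin Sema6d (-0.92). Over their lists alone, the following passed besides Hba-a1 and Hbb-b2: of the escape genes Kdm6a (0.68), and of the X-linked neural genes Ogt (0.74) and Gpm6b (0.78). So did, of the paternally expressed imprinted genes, Mkrn3 (0.81), Nnat (-0.43) and Igf2 (-0.46), and 1 each of the ribosomal (Rpl41, -0.51), respiratory chain (Sdhb, -0.57) and glycolysis and hypoxia (Pfkp, 0.68) lists. No list passed as a whole. 1199 probe sets had an unadjusted p under 0.05, where 435 are expected by chance. The 3' to 5' ratio of Actb was 1.02 to 1.07 in XX_Paf and 1.11 to 1.14 in XX_InX, that of Gapdh 0.727 to 0.767 and 0.738 to 0.817, and the percentage of probe sets at the floor 10.7 to 11.5 and 8.05 to 9.02. Across the 10 arrays the first principal component and the Actb ratio had Pearson r = -0.502 (permutation p = 0.140) and Spearman rho = -0.624 (permutation p = 0.0605), and r = -0.682 without XpO 18 and XX_InX 1, the 1 relation of this kind computed.

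The calls in XX_Paf against XX_InX rested on few arrays. Cmip and Hccs were called with each of the 10 arrays left out in turn, and they were the 2 probe sets called without XX_Paf 1, XX_Paf 2 or XX_Paf 3, where Abcf2 had adjusted p of 0.105, 0.112 and 0.0590. Without XX_InX 1, 7 probe sets were called, of which Cmip, Hccs and Hba-a1 were among the 7 of all arrays (Abcf2 0.118). Without XX_InX 19, 17 were called, of which Cmip, Hccs, Abcf2 and Gsdme were (Hba-a1 0.0842), and without XmO 2 the count was 12, with all 7 among them. Cbx1 also lost its call without XpO 15 (0.0593) or XpO 18 (0.0579), and Cbx1 and Xpo1 both without XmO 7 (0.0723). With the first principal component as a covariate, a choice made after seeing the data, Cmip was the 1 probe set called (Hccs 1.68, adjusted p = 0.0669). The component separates XX_Paf from XX_InX, so as a covariate it takes away part of this contrast.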

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

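The tests of 2 active copies, of 1 Hccs probe set alone (with its condition on background), of all Cmip transcripts, of the cross alone, of RNA quality and of the escape list without Utp14a, and the bounds, were chosen only after the results were seen. The first principal component as a covariate, used below for Hccs and Cmip, was also chosen after seeing the data. The effect of monosomy differed between the crosses for Hccs (difference -1.95, adjusted p = 0.0219; -1.67 in the Paf cross and 0.28 in the In(X) cross) and for Ptprv (difference 5.28 as fitted, adjusted p = 0.0313), which is why both are listed here. The fitted Ptprv value rests on background, since all XX_Paf and XpO arrays were below their brightest Y-linked probe set, and the bound is at least 3.05 (2.39 without XpO 15). The calls of Hccs and Ptprv in this difference depend on the settings. Both ended with no filter, with eBayes without trend, with array weights, with the first principal component as a covariate, and without XmO 2 or XmO 7.

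Hccs was higher in XX_Paf than in XmO. With the first principal component as a covariate, XmO against XX_Paf stayed at -1.63 (95% interval -2.00 to -1.26), which argues against that array-wide axis as the whole cause. For the brighter probe set, 2 active copies in XX as the whole cause are argued against by XpO against XX_InX, at 0.28 (interval -0.12 to 0.69), and by XmO against XX_Paf (-2.00 to -1.34), while the other probe set, at -0.20 (interval -1.18 to 0.78) in XpO against XX_InX, leaves them open. A signal of the brighter probe set alone stays open. The other one was at -1.36 (interval -2.16 to -0.56) in XmO against XX_Paf, but with 2 of 3 XmO arrays below background. In XX_Paf against XX_InX the other one was at 0.41 (interval from -0.49, with 0 inside it). That whole interval lies below the 1.76 of the brighter one, so the probe sets disagree in size there. On every XX_Paf and XX_InX array the other one was above the brightest Y-linked probe set. An allele carried on the X of the C3H/Paf parent may account for the higher Hccs in XX_Paf and stays untested. XX_Paf would hold that X and XmO lack it if the cross is written mother x father. Of the neighbours of Hccs on the X in the GRCm38.p6 table, Gpm6b had a log2 fold change of -0.53 (adjusted p = 0.877) in XmO against XX_Paf. In the same contrast Rab9 had 0.08 and Tmsb4x -0.06.

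The Cmip probe set that fell was lower in both groups of the Paf cross. A change of all Cmip transcripts alike is argued against by the brighter probe set, at -0.23 in XX_Paf against XX_InX (interval -0.43 to -0.03) and with an interval of -0.30 to 0.11 in XmO against XpO. The axis of the first principal component is argued against as the whole cause, since the larger adjusted p of the contrasts was 0.0256 with it as a covariate. A variant under this probe set that differs between the C3H/Paf and In(X)/C3H stocks may account for it. So may a transcript that depends on the direction of the cross, and neither was tested.

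XX_Paf against XX_InX had 1199 unadjusted p-values under 0.05 where 435 are expected by chance. If the cross alone were the source, XmO against XpO should share it: 802 of the 1199 had the same sign there (66.9%), and the median in that direction over the median size was 0.178, from -0.0641 without XpO 18 to 0.423 without XpO 15, on both sides of the 0.319 set as a bound, so the test leaves it open. Over all tested probe sets the fold changes of these contrasts, which share no array, correlated at 0.123. Of 100 splits of the XO arrays and of the XX arrays, 19 gave a correlation at least as high. An axis on which arrays of 1 group also differ is a candidate explanation: across probe sets, which are not independent replicates, XpO 18 less XpO 15 correlated with XX_Paf against XX_InX at -0.372 (XX_InX 1 less 19 at -0.195, XmO 1 less 7 at 0.194). The first principal component of the same data already placed XpO 18 on the side of XX_InX and XpO 15 among XX_Paf. The correlation restates those positions and is not independent support for the axis. RNA quality stays open: the Actb 3' to 5' ratio was 1.02 to 1.07 in XX_Paf and 1.11 to 1.14 in XX_InX, and XmO 2, of lower ratio, less the mean of XmO 1 and XmO 7 correlated with the contrast at 0.00671, which with 1 array excludes nothing. The cross, RNA quality and this axis cannot be told apart for these probe sets with 2 arrays in XX_InX.

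Other splits of the arrays were run within crosses. For the escape list in XO against XX the real mean was -0.34 and the highest size among the other splits 0.330. The real split was the 1 of 60 as large, the smallest share that 60 splits can give. This makes chance less likely but does not exclude it. The same holds without Utp14a, with the real mean at -0.23, the highest other 0.161 and 1 of 60 as large. That shorter list did not pass with an estimated correlation (camera, adjusted p = 0.0540). For the count of probe sets in XO against XX chance stays open: the real count was 1 and the highest other 5, with 25 of 60 splits as large. That 1 probe set is Xist, so the count does not bear on Xist itself, for which 1 of 60 splits was as large (exact p = 0.0167). Chance stays open too for the X-linked less the autosomal median, at -0.00859 with the highest other 0.0545 and 47 of 60 as large. For XmO against XX_Paf the 10 splits are too few for a share under 0.05: the real count was 2 and the highest other 0, and the escape list's real mean was -0.47 and the highest other 0.237, with 1 of 10 as large in each.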

How the results depend on the processing

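The fits with the first principal component as a covariate and without XpO 18 and XX_InX 1 together, and the escape list without Utp14a, were chosen after seeing the data. Intensities near background limit what can be seen: 3727 probe sets were under the filter. Where an array left out leaves 1 in its group, that array is assumed to vary like the other groups. The causes of the changes below were not tested.

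With no filter on low probe sets, 5 were called in XO against XX, 4 in XmO against XX_Paf, 7 in XpO against XX_InX, 3 in XmO against XpO, 5 in the difference between crosses (0 shared) and 17 in XX_Paf against XX_InX (4 shared). Without XpO 18 and XX_InX 1 together these were 3, 2, 3, 0, 1 and 21 (in the last, 4 shared; in the difference, 0), with 420 unadjusted p-values under 0.05 in XmO against XpO over all arrays. A floor at the 25th percentile gave 2 in XmO against XpO, and a filter at the 50th percentile gave 1 in the difference between crosses. The difference had 0 called by limma with eBayes without trend, with array weights and with the first principal component as a covariate, against 514 unadjusted p-values under 0.05 in all arrays, and XX_Paf against XX_InX had 2, 11 and 1. Only the groups of the comparison gave 35 in XX_Paf against XX_InX; this has no counterpart for XO against XX and the difference, which use all groups. Replicate numbers did not pair the arrays (XmO 1 with XX_Paf 1, r = -0.0123 and XmO 2 with XX_Paf 2, r = -0.0415, across probe sets, which are not independent replicates); the shared numbers as a fixed block gave 1 in XmO against XX_Paf, where Hccs lost its call (-1.60, adjusted p = 0.369), and a random block gave 1 in XO against XX and 2 in XmO against XX_Paf.

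Lists past the threshold were 5 in XO against XX, 4 in XmO against XX_Paf, 2 in XmO against XpO and 2 in the difference with all probe sets of a gene as members; 3, 2 and 1 in the last 3 of these with the mean of all probe sets; 5 in XO against XX and 3 in XpO against XX_InX without XpO 18 and XX_InX 1 together; 2 in XO against XX, 5 in XmO against XX_Paf, 3 in the difference and 3 in XX_Paf against XX_InX with the component as a covariate; and 0 in XmO against XpO with an estimated correlation, where the cell cycle list had mean -0.23 and adjusted p = 0.225 (mean -0.20 and 0.110 without XpO 18 and XX_InX 1 together). The escape list without Utp14a had mean -0.23 in XO against XX and -0.30 in XmO against XX_Paf, past the threshold in both with the preset correlation and in neither with an estimated one (adjusted p = 0.0540 and 0.0951), while all 6 genes passed in both.

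With each array left out, called probe sets ran from 1 to 3 in XO against XX, 2 to 4 in XmO against XX_Paf, 1 to 4 in XpO against XX_InX, 1 to 7 in XmO against XpO, 0 (without XmO 2, XmO 7 or XX_InX 1) to 4 (without XpO 18) in the difference and 2 (without each XX_Paf array) to 17 (without XX_InX 19) in XX_Paf against XX_InX. Lists past the threshold ran from 1 to 8 (without XpO 18), 1 to 5 (without XX_Paf 1), 0 to 2 (without XpO 18), 1 to 2 (without XpO 15), 0 to 3 (without XpO 15 or XX_Paf 1) and 0 to 1 (without XX_Paf 1). The escape list's mean ran from -0.42 to -0.27 in XO against XX and from -0.51 to -0.43 in XmO against XX_Paf, past the threshold each time, and the cell cycle list's in XmO against XpO from -0.25 to -0.20, with adjusted p up to 0.0948 (without XpO 18). The X-linked less autosomal median in XO against XX ran from -0.0188 to 0.0372. Of 2328 values of named genes and lists under the alternatives, 2247 stayed on their side of the threshold (43 of these, with neither value past it, changed sign), 71 lost the threshold, 10 gained it and 0 turned direction while past it. Most named genes were not past the threshold with all arrays and the settings fixed beforehand, so they could not lose it. Leaving out an array outside a contrast also left its estimate unchanged. The share that stayed therefore does not measure how stable the calls were.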

Other observations

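The fits with the first principal component as a covariate and without XpO 18 and XX_InX 1 together, the genes outside the fixed lists and the probe set shared by several Xlr genes were chosen after the results were seen. The pseudoautosomal gene Erdr1 was at 5007 ± 718 in XmO, 5612 ± 1434 in XX_Paf, 9976 ± 3651 in XpO and 12214 ± 9899 in XX_InX (XX_Paf against XX_InX -0.87, limma adjusted p = 0.374; -1.81, adjusted p = 0.0428, without XX_InX 19 and 0.08 without XX_InX 1), and its second probe set had -0.04. The Y-linked genes Eif2s3y, Kdm5d, Uty and Sry were under the filter, with group means of at most 23.7 for Eif2s3y, 15.3 for Kdm5d, 48.4 for Uty and 100.2 for Sry. Xlr4a, of a family of X-linked lymphocyte-regulated genes, was also under it, at 56.4 in XmO, 9.87 in XX_Paf, 15.7 in XpO and 42.8 in XX_InX. So were the escape genes Pbdc1 and Mid1 (XX_Paf 10.4, 56.3 and 77.5, with means of 11.9 in XmO, 12.7 in XpO and 12.9 in XX_InX). A tested probe set shared by several Xlr genes, which names none of them, was at 232 ± 156 in XmO, 99.5 ± 106 in XX_Paf, 72.3 ± 22.6 in XX_InX and 16.3 ± 1.06 in XpO (XmO against XpO, limma adjusted p = 0.521). All XpO and XX_InX arrays, and XX_Paf 2, were below their brightest Y-linked probe set.

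With all arrays and the settings fixed beforehand, markers of cell types and regions did not pass as lists in any contrast. Under the alternatives some did. In XO against XX these were meninges (all probe sets as members, the first principal component as a covariate, and without XpO 18, XX_Paf 3, or XpO 18 and XX_InX 1 together), muscle and skin (all probe sets as members, and without XmO 1, XX_Paf 1 or XX_Paf 3), forebrain (all probe sets as members), microglia (without XpO 18, alone or with XX_InX 1), pituitary (without XpO 18) and erythroid markers (without XX_InX 1). In XmO against XX_Paf they were meninges (mean of all probe sets, all as members, and the component) and muscle and skin (without XX_Paf 1). In XpO against XX_InX they were microglia (without XpO 18, alone or with XX_InX 1) and meninges (without both), and in XmO against XpO meninges (mean of all probe sets, all as members, and without XpO 15). Diencephalon passed in the difference between crosses (all probe sets as members, and without XX_InX 1 or XX_Paf 1) and erythroid markers in XX_Paf against XX_InX (the component). In XO against XX, neuron markers had a mean log2 fold change of -0.01 (camera, adjusted p = 0.762), progenitors -0.04 (0.349), astrocytes -0.08 (0.344), microglia -0.07 (0.344), meninges -0.08 (0.0599), and muscle and skin -0.33 (0.0599). Synaptic genes had 0.04 (0.434), immediate early genes 0.04 (0.762), and imprinted genes expressed from the paternal and maternal alleles -0.10 (0.186) and -0.04 (0.730). Under the alternatives, the paternally expressed list passed in XO against XX with all probe sets as members, and in fits without XpO 18 or XX_InX 1. The X-linked neural list passed only in fits without XpO 18, which leave 1 XpO array (XO against XX, XpO against XX_InX and XmO against XpO).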
